A study of Homo sapiens with 2 samples.

How the data were processed

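Poly(A)-selected RNA extracted with Trizol was sequenced from CAL-62 cells of 2 transfections, a negative control and a LINC00886 silencer, with 1 library each. Groups were taken from the transfection label of each sample. The deposited table gives counts of reads per gene, that is 41765 gene symbols with a gene type and a whole number for each library. The file is named for FPKM, but every value is a whole number and the column totals differ, so the values were treated as raw counts. HISAT2, featureCounts and the hg38 build are named per the submitters' processing notes. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, paralogs and pseudogenes may have been split or shared.

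Counts were divided by the library total of 17259713 in the control and 22845100 in the silencer library and multiplied by 1000000 to give CPM. The design fixed before the data were examined had assumed FPKM. CPM took its place, with the same pseudocount of 1, the same minimum means of 1 and 5 and the same threshold of 2-fold. Since a gene's length is the same in both libraries, it cancels in a ratio apart from the effect of the pseudocount. Log2 ratios are of silencer CPM + 1 over control CPM + 1 and understate the ratio of rare genes, while folds are plain ratios of CPM. Of the gene symbols, 21882 had a count in either library, and 13424 with a mean of at least 1 CPM were called measured. Intervals are exact: Poisson for a level and conditional binomial (Clopper-Pearson) for a ratio, at 95%. With no replicates no test across genes was run, and edgeR and DESeq2 served only to supply scaling factors.

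The text names LINC00886, the 12 mRNA genes with the highest and the 12 with the lowest log2 ratio at a mean of at least 5 CPM, and the 3 highest and 3 lowest genes of other types. It also names the 5 most abundant genes. The rule further covered the measured neighbours of LINC00886 and 2 to 4 members of each list among its 2 highest and 2 lowest, of which the text names only some. OAS3 is named outside the rule, as a gene shared between lists. Members of gene families named only in the closing section lie outside this rule and were picked after their values were seen. The gene lists, 43 in number, were fixed at the same time as that rule. The results of 1 list and of a few genes are not reported here, although the counts of lists include that list. 1064 of their 1066 symbols were found in the table, 37 of them under an older symbol or a short mitochondrial name. For each list with at least 5 measured members the median was placed among the medians of 10000 random lists. These were drawn from other measured genes in the same of 20 expression bins, and for the length-matched percentile from 10 expression bins with 10 exon-length bins each. A list stood above from percentile 97.5 and below up to percentile 2.5. Percentiles describe these libraries and are not a test between conditions.

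Coordinates, exon lengths, GC content, coding regions and 3′ UTRs came from GENCODE 29 on GRCh38, in which 30098 symbols of the table were found by name. 90.9% of the measured genes had an exon length, which counts each annotated exon base of a gene once over all its transcripts. Every 7-mer present in the 3′ UTRs of at least 50 genes was compared between genes with and without it over 9516 mRNA genes with a mean of at least 5 CPM and a 3′ UTR of at least 50 bases. A linear model adjusted the ratios for UTR length and composition, expression and Alu repeats.

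The procedures were tested on simulated data. For the 2-fold rule, counts were drawn at the real means and library sizes, while the list and 7-mer checks used real or permuted ratios. The 200 changed genes, among 13407 measured, all had a mean of at least 5 CPM. The 2-fold rule recovered 100.0% of those with a 4-fold and 99.0% of those with a 3-fold difference. Recovery of genes from 1 to 5 CPM was not tested, and the pseudocount shrinks their ratios most. With no gene changed the rule called 0 of 13435 genes, so Poisson counting error alone gave no 2-fold gene. The simulation held no variation between cultures or from PCR, so its 0 cannot show that the called genes exceed such variation. Over 3464 genes with 5 to 30 counts in all, the variance between the real libraries was 1.65 times that of counting error, true differences included. Of 400 random lists of 25 genes 4.0% lay beyond either bound, and all 100 lists with a planted shift of 0.5 were recovered. A 7-mer planted with a shift of -0.1 ranked lowest of all 7-mers.

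Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a minimum of 5 CPM, centring on the median or on a mean trimmed by 30% at each end, TPM, mRNA genes only, a threshold of 1.5-fold, list means and 10 expression bins. The closing section gives their effect and that of alternatives chosen later. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.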

Results

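The data collected were 2 RNA-seq libraries made from poly(A)-selected RNA of CAL-62, an established cell line derived from an anaplastic thyroid carcinoma. 1 library came from cells given a negative control and 1 from cells given a smart silencer against LINC00886, which is a commercial mixture of siRNAs and antisense oligonucleotides. The comparison addresses which transcripts differ when this long noncoding RNA is silenced. The control library held 17259713 gene counts over 19787 genes with a count, and the silencer library held 22845100 over 20605. With 1 library per group the differences have no replicate check, so they describe these libraries and no p-value is given. Intervals are exact 95% intervals that cover counting error only. They treat reads as independent molecules, which PCR reads are not, so they may be too narrow even for that error.

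LINC00886, the targeted transcript, is annotated as a long intergenic noncoding RNA on the minus strand of chromosome 3, from 156747346 to 156817062 (GRCh38). Its level was 1.97 CPM (counts scaled to equal library totals) in the control library, from 34 counts (interval 1.36 to 2.75). The silencer library gave 0.394 CPM from 9 counts (interval 0.180 to 0.748). The level was thus 5.0-fold lower with the silencer (interval 2.35 to 11.9), with a log2 ratio of -1.09 after a pseudocount of 1 CPM. The transcript was rare in both libraries, and the floor set by 3 counts was 0.174 CPM in the control and 0.131 CPM in the silencer library.

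The 12 mRNA genes with the highest ratios in the silencer library included the extracellular matrix genes LAMA4, FN1, FBN1 and NID2. LAMA4, a laminin chain of basement membranes, was at 2.72 CPM in the control and 30.7 CPM in the silencer library, 11.3-fold higher (interval 8.38 to 15.5). FN1, which encodes fibronectin, was already abundant in the control at 1401 CPM and reached 8339 CPM with the silencer, 5.95-fold higher (interval 5.87 to 6.03). PODXL, a cell-surface sialomucin, stood at 60.6 and 444 CPM, and FBN1, the main protein of microfibrils, at 7.07 and 52.4 CPM. Ligands and their regulators accompanied them: INHBA, a subunit of activin, was 7.15-fold higher (interval 6.04 to 8.51), GREM1, an antagonist of bone morphogenetic proteins, 5.78-fold (interval 5.29 to 6.34) and SLIT2, a guidance ligand, 5.21-fold (interval 4.27 to 6.42). LTBP1, which binds latent TGF-beta, was 6.10-fold higher, the basement membrane gene NID2 6.46-fold, the fibulin gene EFEMP1 4.92-fold, the metalloprotease gene ADAM19 4.91-fold and the nucleotide receptor gene P2RY6 7.02-fold.

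The lowest ratios belonged to C12orf57, IL11 and RND2. C12orf57 was at 150.9 CPM in the control and 25.3 CPM in the silencer library, 5.97-fold lower (interval 5.45 to 6.54). IL11, a cytokine, was 5.10-fold lower (interval 4.10 to 6.40), and RND2 was 4.81-fold lower (interval 3.66 to 6.39). The retinoic acid carrier gene CRABP2 stood at 121 and 30.8 CPM, the membrane protein gene LRRC15 at 24.4 and 5.997 CPM, and the creatine kinase gene CKB at 17.7 and 4.68 CPM. S100A10, an annexin partner, was 2.90-fold lower, the elastase inhibitor gene PI3 3.72-fold lower, the glycolysis regulator gene PFKFB4 3.36-fold lower and the autophagy gene TP53INP2 2.92-fold lower. TM4SF19 was 4.30-fold lower, and PAPL, which had no match in the annotation used, was 2.79-fold lower. In GRCh38, LAMA4 lies on chromosome 6 (112108760 to 112254939), FN1 on chromosome 2 (215360440 to 215436172), C12orf57 on chromosome 12 (6942978 to 6946003) and IL11 on chromosome 19 (55364389 to 55370463).

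**Figure D1:**
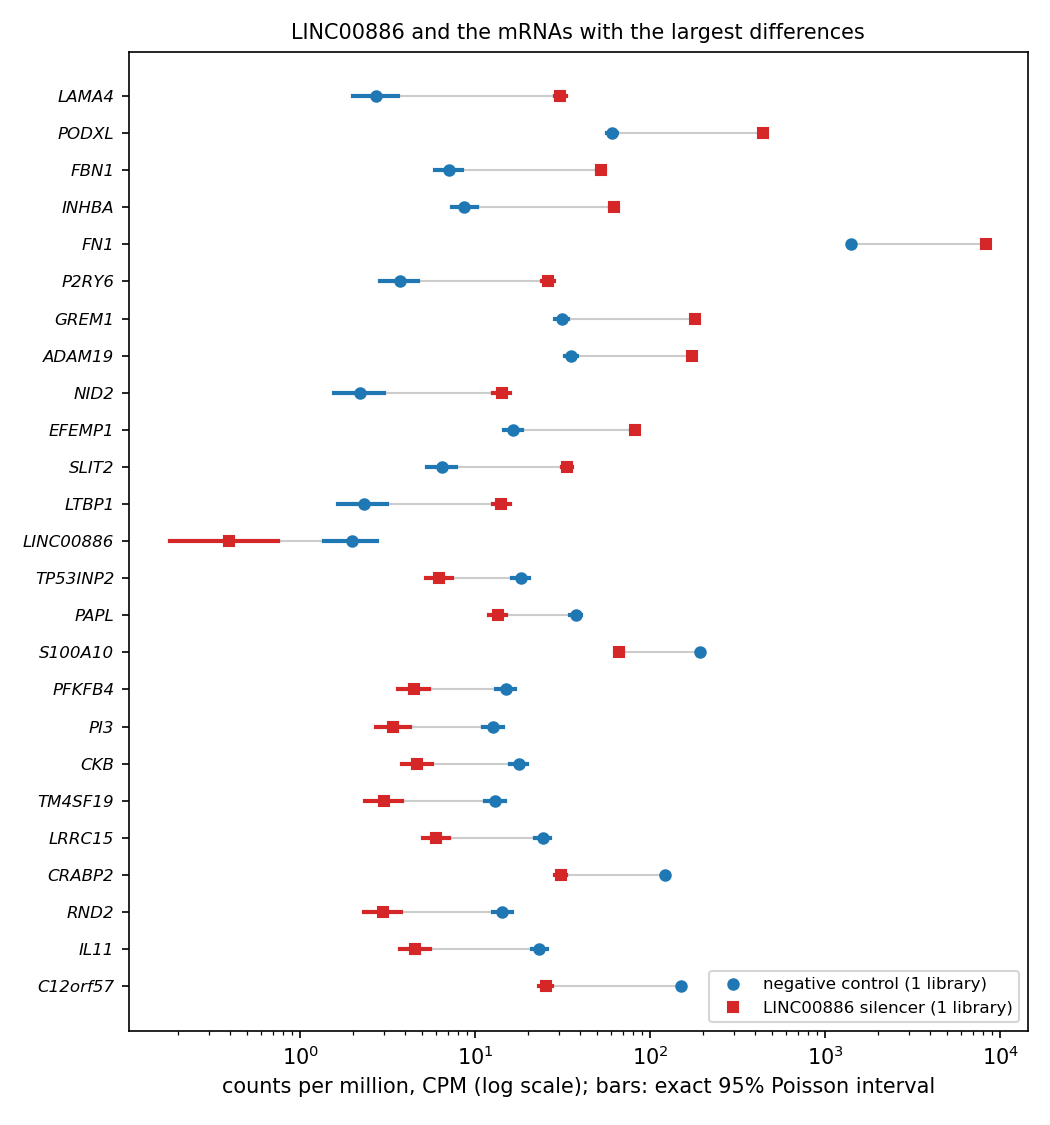
CPM (log axis) of LINC00886 and of the 12 mRNA genes with the highest and the 12 with the lowest ratio, in the negative control (blue circles) and LINC00886 silencer (red squares) libraries, 1 library each. Bars are exact 95% Poisson intervals, and LAMA4, at 2.72 and 30.7 CPM, shows the widest gap among the higher genes.

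Of 13424 genes with a mean of at least 1 CPM, 332 were at least 2-fold higher in the silencer library and 120 at least 2-fold lower on the scale with the pseudocount. The higher genes made up 73.5% of these, and 62.4% once the ratios were centred on their median (257 and 155 genes). Among the higher genes 324 were mRNAs, and among the lower genes 99. The median log2 ratio of the measured genes was 0.09, with an interquartile range of -0.17 to 0.35. The ratio also followed gene length: its median was -0.21 in the shortest of 10 groups of mRNA genes ordered by exon length and 0.29 in the longest. Spearman's rank correlation across 11357 mRNA genes was 0.338, and genes are not independent replicates. Gene lists are therefore given with their percentile among 10000 random lists of the same size matched on expression, and again among lists matched on expression and exon length.

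**Figure D2:**
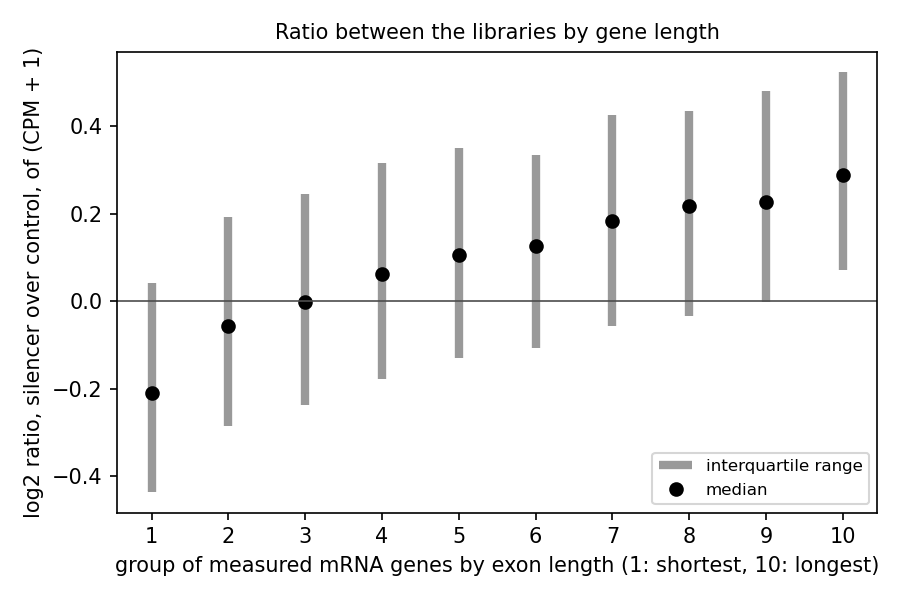
Median (points) and interquartile range (bars) of the log2 ratio of CPM + 1, silencer over control, in 10 equal groups of the measured mRNA genes ordered by exon length. The medians go from -0.21 in the group of shortest genes to 0.29 in the longest.

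Collagen and basement membrane genes were the list with the highest median. All 26 measured members had a ratio above 0, 14 were at least 2-fold higher, and the median log2 ratio was 1.05 (percentile 100 in both matchings). Mesenchymal genes and regulators of the epithelial-mesenchymal transition had a median of 0.70, with 20 of 24 above 0 and 7 at least 2-fold higher (percentile 100 in both). FN1 and FBN1 led them, while S100A4 (log2 -0.72) and SNAI1, a transcriptional repressor of E-cadherin (log2 -0.39), were lower. Integrins, the receptors for matrix proteins, had a median of 0.73 (percentiles 100 and 99.99 with length matching). ITGA6 stood at 70.7 and 170 CPM and ITGA11, a collagen receptor subunit, at 1.16 and 4.95 CPM, while ITGA7 was lower at 4.92 and 2.32 CPM. Epithelial junction and keratin genes were not lower as a group: their median was 0.31 (percentiles 99.4 and 99.6), with the protease gene ST14 at log2 1.33 and the tight junction gene CLDN4 at log2 -0.64. The list passed the upper bound in 10 of 14 alternative settings, and its lowest percentile was 93.4, with no filter. The median was then 0.13, and it was 0.20 with a pseudocount of 5 (percentile 95.2). Extracellular proteases and their inhibitors had a median of 0.24, within the random range (percentiles 96.8 and 85.2). The list passed the upper bound by its mean of 0.48 (percentile 100), with no filter (percentile 99.4) and among genes of at least 5 CPM (percentile 98.8). Their SERPINE2, an inhibitor of serine proteases, was at 14.8 and 66.8 CPM, and the collagenase gene MMP1 at 2.32 and 1.14 CPM.

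Several lists of signalling genes also stood above matched random lists. The WNT and NOTCH lists mix targets with pathway components, and the receptor tyrosine kinase list holds receptors and ligands. Their medians thus do not by themselves measure target output. The WNT target SP5 (log2 -0.45) and the NOTCH target HES4 (log2 -0.46) were lower, while 15 of 19 WNT and 8 of 10 NOTCH members were above 0. TGF-beta targets had a median of 0.47 (percentiles 99.99 and 100) and 5 of 20 members at least 2-fold higher. The matrix adaptor TGFBI was at 7.36 and 29.7 CPM beside INHBA, whereas ID1 and ID3, inhibitors of basic helix-loop-helix factors, had log2 ratios of -0.74 and -0.67. WNT targets and components had a median of 0.51 (percentile 99.99 in both), or 0.24 with no filter (percentile 98.1), with the receptor gene FZD1 at log2 1.38 and the antagonist gene SFRP1 at 1.24. CCND1, which encodes cyclin D and belongs to the WNT and the MAPK list, was at 598 CPM in the control and 227 CPM in the silencer library. Receptor tyrosine kinases, the EGFR family and their ligands had a median of 0.50 (percentiles 100 and 99.98), led by VEGFC at 7.07 and 27.2 CPM. NOTCH genes had a median of 0.43 (percentiles 99.2 and 99.0, and 94.2 for the mean in place of the median), with the ligand gene JAG1 at log2 1.17 and LFNG at log2 -0.90. YAP and TAZ targets had a median of 0.35 (percentiles 99.8 and 99.7), or 0.20 with ratios corrected for length (percentile 94.7), with CCN2 at log2 0.89 and ANKRD1 at log2 -1.08. Immediate early and AP-1 genes had a median of 0.32 (percentiles 99.9 and 100), with KLF4 at log2 1.64 and ATF3 at log2 1.45. MAPK output genes lay within the random range, with a median of 0.07 (percentiles 65.7 and 77.7).

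Interferon-stimulated genes were moderately higher. Their median log2 ratio was 0.42, with 27 of 31 measured members above 0 and 6 at least 2-fold higher (percentiles 100 and 99.99). OAS2, an antiviral synthetase activated by double-stranded RNA, was at 5.74 and 21.5 CPM, and IFI44 at 4.17 and 14.5 CPM. ISG15, a ubiquitin-like protein induced by interferon, was lower at 41.2 and 31.2 CPM, as was ISG20 at 59.9 and 40.4 CPM. Sensors of double-stranded RNA had a median of 0.51 over 10 members (percentiles 99.8 and 98.9, and 97.05 among genes of at least 5 CPM). This list shares OAS1, OAS2 and OAS3 with the interferon-stimulated genes, and these were its 3 members at least 2-fold higher, so the lists are not separate evidence. MHC class I presentation genes had a median of 0.52 with 18 of 20 above 0 (percentile 100 in both), among them the peptide-trimming gene ERAP1 at 23.8 and 69.5 CPM and the transactivator NLRC5 at 9.91 and 24.2 CPM. NF-kB targets, cytokines and chemokines went both ways, with 3 members at least 2-fold higher and 4 at least 2-fold lower. Their TNF was at 1.51 and 8.45 CPM, while IL11 and CSF3, a granulocyte growth factor, were at log2 -2.13 and -1.39. The list's median of 0.18 was within the random range by expression (percentile 91.2) and above it by length matching, where the median of the 27 members with a length was 0.23 (percentile 99.7). Its mean was 0.08 (percentile 51.1), and its median 0.11 among genes of at least 5 CPM (percentile 74.1) and 0.32 in TPM (percentile 98.2).

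The 6 lists that stood below expression-matched random lists were those of cytosolic ribosomal proteins, small nucleolar RNA host genes, the nuclear-encoded respiratory chain, glycolysis, cholesterol synthesis and metallothioneins. All 55 cytosolic ribosomal protein genes had a ratio below 0, with a median log2 ratio of -0.50 (percentile 0.0 in both matchings). RPS20 was at 1220 and 568 CPM, and RPL6 at 939 and 835 CPM. Small nucleolar RNA host genes had a median of -0.55 (percentile 0.0), which was -0.46 over the 16 members with a length (percentile 0.03 with length matching), -0.34 in TPM and -0.29 with ratios corrected for length, with ZFAS1 at 146 and 67.1 CPM. Nuclear-encoded respiratory chain genes had 38 of 40 members below 0 and a median of -0.39 (percentile 0.0). With length matching, the 33 members with a length had a median of -0.36 (percentile 0.03), and the list's median was -0.25 in TPM and with ratios corrected for length. ATP5F1A, a subunit of ATP synthase, was at 472 and 235 CPM. Glycolysis genes had a median of -0.38 with 16 of 19 below 0 (percentiles 0.03 and 0.0). PGK1 stood at 1278 and 676 CPM, and PFKL went the other way at 49.8 and 86.4 CPM. Cholesterol synthesis and uptake genes had a median of -0.31 with 19 of 24 below 0 (percentile 0.0 in both), or -0.19 in TPM. TM7SF2 and MSMO1, both sterol-synthesis enzymes, were at log2 -1.14 and -1.09, and SQLE was at 0.35. Metallothionein and metal transport genes had a median of -0.28 (percentile 0.85, and 5.61 with length matching), or -0.15 with a pseudocount of 5 (percentile 3.66) and -0.79 among genes of at least 5 CPM, with MT1X at 53.01 and 20.1 CPM and the transferrin receptor gene TFRC at 298 and 424 CPM. The length trend ran in the same direction as the medians of the short ribosomal protein and respiratory chain genes. Length-matched random lists had medians of -0.07 for the former and -0.10 for the latter.

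**Figure D3:**
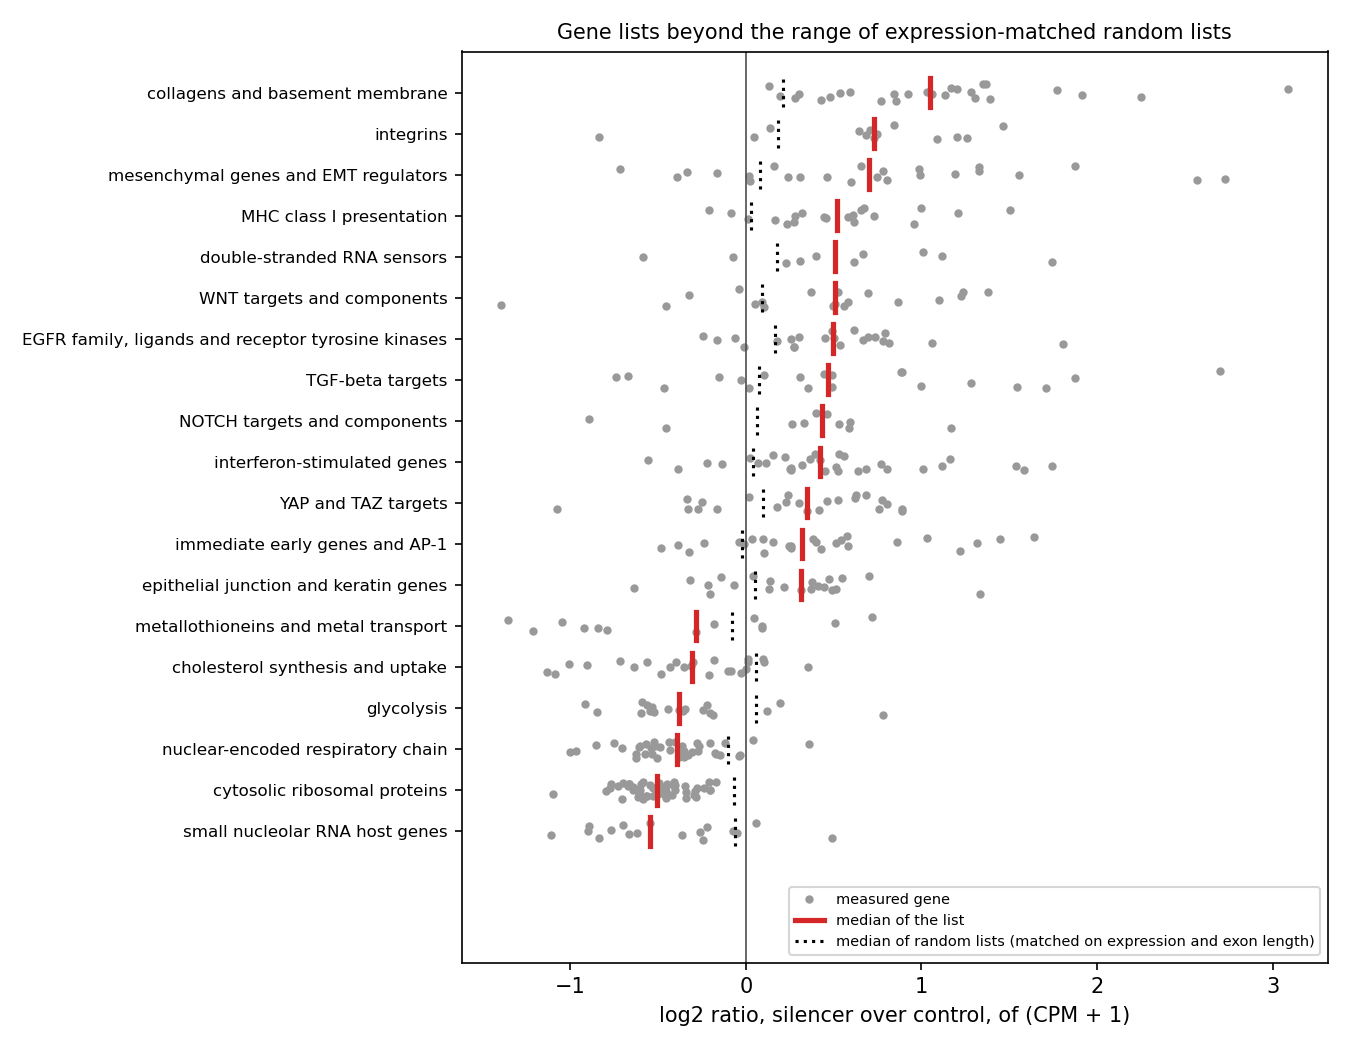
Log2 ratios of CPM + 1, silencer over control, for the measured genes (grey points) of 19 gene lists beyond the range of expression-matched random lists, with the median of each list (red) and of random lists matched on expression and exon length (dotted). The medians go from -0.55 for small nucleolar RNA host genes to 1.05 for collagens and basement membrane.

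In all, 14 of 40 lists with at least 5 measured members stood above and 6 below the expression-matched random lists, against about 1 on each side by chance. With length matching 17 stood above and 7 below, and 13 and 5 did so in both. Stress lists were among those that depended on the matching. Targets of ATF4 and the integrated stress response had a median of 0.16 (percentiles 91.4 and 98.6), with ATF3 at 16.3 and 46.0 CPM and the pro-apoptotic factor DDIT3 at 24.4 and 13.8 CPM. Endoplasmic reticulum chaperones had a median of 0.21 (percentiles 96.5 and 99.1), with 17 members above 0 and 7 below. HSPA5, the main chaperone there, was at 640 and 988 CPM and EDEM1 at 92.1 and 63.4 CPM. Fatty acid synthesis and lipid storage genes had a median of -0.11 (percentiles 2.99 and 0.70), or 0.02 in TPM, with ME1 at log2 0.92 and LPIN1 at log2 -0.54. The siRNA and antisense machinery list, which also holds genes of microRNA processing, had a median of -0.01 (percentiles 21.7 and 2.45). In TPM the median was 0.11 (percentile 23.03). The microprocessor gene DROSHA was at log2 0.61 and TARBP2 at log2 -0.54. Mitochondrially encoded mRNAs had a median of -0.02 (percentiles 59.7 and 99.98). It was 0.10 in TPM (percentile 94.7) and 0.30 with ratios corrected for length (percentile 99.8). The cytochrome b gene was at log2 0.29 and MT-ND3 at log2 -0.45. Random lists had a median of -0.05 by expression and -0.40 with length matching, so the higher percentile came from lower comparison genes.

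Proliferation genes were close to the other genes. G1/S and DNA replication genes had a median of 0.04 (percentile 39.2, and 76.0 with length matching). G2/M and mitosis genes had a median of 0.11 (percentiles 77.9 and 94.7), with 26 members above 0 and 14 below. Among the latter list, the survivin gene BIRC5 was at 109 and 183 CPM and PTTG1 at 329.4 and 233.5 CPM. Targets of p53 had a median of -0.08 (percentile 2.87, and 2.25 among genes of at least 5 CPM), which was -0.04 over the 24 members with a length (percentile 13.7). The median was above 0 in TPM (0.07, percentile 7.49) and with ratios corrected for length (0.05, percentile 29.95). CDKN1A, a cyclin-dependent kinase inhibitor, was at 160.5 and 79.1 CPM and FAS at 4.29 and 8.97 CPM. Apoptosis regulators had a median of 0.11 (percentiles 60.0 and 71.3). MYC and ribosome biogenesis genes had a median of -0.02 and a mean of 0.02 (percentile 23.2, and 28.2 with length matching), with NOLC1, a nucleolar chaperone, at 99.0 and 252 CPM. Hypoxia targets had a median of 0.10 and a mean of -0.03 (percentile 53.1, and 26.4 with length matching), with ERO1A at log2 0.92 and SLC2A3 at log2 -1.12. NRF2 targets had a median of 0.01 and a mean of -0.01 (percentiles 28.8 and 55.5), with the ferritin gene FTL at 1617 and 935 CPM. Heat shock genes had a median of 0.03 (percentiles 56.5 and 60.6), and lysosome and autophagy genes one of 0.15 (percentiles 89.6 and 83.6), with the protease gene CTSB at log2 0.73 and the autophagy receptor gene SQSTM1 at log2 -0.73.

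Thyroid differentiation genes were mostly below 1 CPM. Of 21 genes 7 were measured, with a median log2 ratio of 0.40 (percentiles 95.03 and 94.2). With no filter on low values the median was 0.02 (percentile 30.5). PAX8, a thyroid transcription factor, was at 438 and 442 CPM, GLIS3 at 2.67 and 6.65 CPM and the peroxide-generating oxidase DUOX1 at 1.85 and 3.63 CPM. Most markers of other cell types were below 1 CPM as well. Of 16 immune markers 4 were measured, led by the lysosomal gene CD68 at 62.0 and 49.0 CPM, with a list median of -0.32. Of 12 endothelial markers 2 were measured (median 0.20), with ESAM at 11.1 and 10.9 CPM. Of 12 fibroblast and stromal markers 3 were measured (median 0.53), and COL1A1 among them was at 77.3 and 189 CPM.

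Genes near LINC00886 on the long arm of chromosome 3 had a median log2 ratio of 0.19 over 16 measured members (percentiles 82.0 and 72.5). SLC33A1, an acetyl-CoA transporter gene, was the highest at 19.4 and 43.4 CPM, followed by PLCH1 at 2.14 and 4.42 CPM. SSR3, a subunit of the translocon-associated complex, was the lowest at 696 and 549 CPM. LEKR1 stood at 1.04 and 1.23 CPM, and TIPARP at 80.8 and 101 CPM.

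Among other noncoding genes, HCP5, a transcript of the MHC class I region, was 4.89-fold higher (interval 3.31 to 7.44). LINC00667 was 2.30-fold higher and LOC102724129 2.04-fold, with a log2 ratio of 1.02 that was 0.93 once centred on the median. UCA1, a noncoding RNA abundant in carcinoma lines, was at 307 CPM in the control and 132 CPM in the silencer library. TM4SF19-TCTEX1D2 (3.55-fold lower) overlaps TM4SF19 and RPS3AP21 (2.61-fold lower) is a ribosomal protein pseudogene, so both ratios are uncertain. The list of long noncoding RNAs with nuclear roles or cancer links had a median of 0.07 (percentile 49.8, and 24.6 with length matching), with TUG1 at log2 0.74. The most abundant genes were the mitochondrial COX1 (7887 and 9380 CPM), GAPDH (9296 and 6166 CPM), EEF1A1 (7567 and 6350 CPM), HMGA1 (6442 and 6715 CPM) and ACTB (6015 and 6528 CPM).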

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

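Scaling by TMM or DESeq2 factors, correction for exon length and length matching were chosen only after the data had been seen, and the other alternatives were fixed beforehand. The 332 higher and 120 lower genes became 565 and 224 with a pseudocount of 0.1, 139 and 33 with a pseudocount of 5, 526 and 219 in TPM, and 1472 and 701 at a threshold of 1.5-fold. A smaller pseudocount and a lower threshold let more genes pass, and a larger pseudocount fewer, by construction. Correction for exon length left 297 higher and 67 lower genes, and for it and for TPM the cause was not tested. Under the other settings the counts stayed within 1.5 times, at 249 to 336 higher and 86 to 155 lower genes. TMM gave 261 and 153 and DESeq2 factors 260 and 154. The log2 ratio of LINC00886 was -2.07 with a pseudocount of 0.1 and -0.37 with 5, and with its 34 and 9 counts the depth limits its precision. Of 208 ratios of other named genes under an alternative, 200 kept their direction and side of the threshold and 8 no longer reached it. For the gene lists, 528 medians kept their side of the bounds, 19 newly passed one and 10 no longer did, and none turned from above to below or the reverse. Centring takes the same amount from every gene and cannot move a percentile. TMM and DESeq2 factors can move it only through the pseudocount and the filter. Part of the 528 was thus fixed in advance and is no sign of stability. Lists that lost their place under some setting included the epithelial, double-stranded RNA sensor, NOTCH, YAP and TAZ and metallothionein lists. The median log2 ratio of all measured genes was 0.09 in CPM and 0.18 in TPM. Several medians close to 0 of lists within the random range, such as those of G1/S, MAPK, MYC, NRF2, p53 and mitochondrially encoded genes, changed sign with the scaling.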

Other observations

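The gene families below were formed after the data had been seen, and the tests chosen only after the result was seen were those of seed pairing of the silencer and control siRNAs, of sites in coding regions, of TCGGAGA in the collagen genes and of 7-mers among genes without TCGGAGA. Families were grouped by symbol prefix outside the fixed lists and set against lists matched on expression and exon length, and of 181 families 16 lay above and 14 below the bounds, against about 4.5 on each side by chance. Genes of the mitochondrial ribosome were lower with the silencer as were those of the cytosolic one. Of 48 genes of its large subunit (MRPL) 44 had a ratio below 0, as had 22 of 31 of the small (MRPS), with a median of -0.30 against -0.11 in random lists (percentile 0.06). The small subunit genes had a median of -0.25 (percentile 1.34). MRPL52 was at 137 CPM in the control and 85.8 CPM in the silencer library. RNA polymerase subunit genes (POLR, 20 of 28 below 0) had a median of -0.20 (percentile 0.49), and exosome genes (EXOSC, 7 of 10 below 0) one of -0.29 (percentile 1.37). Over median centring, TMM, DESeq2 factors and TPM the medians went from -0.40 to -0.19 for MRPL, -0.35 to -0.13 for MRPS, -0.30 to -0.08 for POLR and -0.39 to -0.18 for EXOSC.

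Carbohydrate sulfotransferases (CHST), which add sulfate to chondroitin and other glycans, had a median log2 ratio of 0.98 over 9 genes, of which 8 were above 0 and 5 at least 1.5-fold higher (percentile 100). CHST11 stood at 31.6 and 97.4 CPM and CHST15 at 2.49 and 9.15 CPM, with CHST12 at log2 -0.10. The GALNT enzymes, which start O-linked glycosylation, had a median of 0.53 over 11 genes, of which 9 were above 0 and 5 at least 1.5-fold higher (percentile 99.6), with GALNT10 at 79.8 and 173 CPM. The 406 zinc finger genes (ZNF), of which 321 were above 0, had a median of 0.23 against 0.13 in random lists (percentile 100). These 3 medians stayed above 0 under the same scalings. All 12 measured gamma-protocadherin genes (PCDHGA) were above 0 with a median of 0.79, but they share their last exons and so their reads.

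The collagen, basement membrane and mesenchymal genes were higher with the silencer. The trend with exon length is not the whole cause: among lists matched on it the collagen list was at percentile 100 and the mesenchymal list at percentile 100. Fibroblasts in the culture would bring all of their abundant transcripts, yet COL1A1, COL1A2, COL3A1, DCN and LUM together gained 116.6 CPM where FN1 gained 6938, and DCN, LUM and COL3A1 stayed at or below 0.0876 CPM in both libraries. Direct pairing of the control siRNA with TCGGAGA, weighed below, is not the cause for the 20 of 26 collagen and basement membrane genes that lack it in the 3′ UTR and coding region, as their median of 0.98 (quartiles 0.58 and 1.22, all above 0) was 0.89 above that of all genes, while it stays open for the 6 with it in the coding region only (median 1.56), and an indirect effect or pairing with other sites stays open for all. An effect of LINC00886 loss, another effect of the silencer and a difference between the cultures may each account for the pattern, and 1 library per group leaves these open.

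Ribosomal protein and respiratory chain genes were lower, in the direction of the length trend. Matched on expression and exon length, the ribosomal protein list was still at percentile 0.0 and the respiratory chain list at percentile 0.03. Matched on expression and GC content, the lists were at percentile 0.0 and 0.0. Neither trend, as measured, can thus be the whole cause. Exon length covers all annotated exons of a gene and can exceed the length of its mRNA, so a trend with mRNA length stays open. A difference in RNA quality or library preparation that acts on short transcripts, and a biological difference, also stay possible and untested.

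Of 16147 7-mers scanned in 3′ UTRs, TCGGAGA had the highest standardized value (8.13, 209 genes, adjusted log2 difference 0.22) and GTGACTT (-7.79, 1478 genes, -0.09) and CTCTCAT (-6.23, 1137 genes, -0.08) the lowest; some 7-mers that share 5 or more bases with them, among them GGAGAAA (7.45), CGGAGAA (6.66), ATGGAGA (5.38) and TGTGACT (-5.35), also lay beyond the 4.52 and -4.10 reached by those that share fewer. For the first 3, GC content and a site anywhere in the mRNA do not account for the whole shift. The shift of the reverse complements, which have the same GC content, was at most 0.217 of theirs. That of genes with only a coding site was at most 0.397. The 3 7-mers were picked as extremes in these same data, which by itself favours smaller shifts in the sites they are compared with. The 764 genes with only a coding TCGGAGA were higher too (median 0.28 against 0.18). Reverse complements do not test other features of composition such as purine content, which were left to the adjustment in the linear model. A candidate explanation for GTGACTT and CTCTCAT is seed pairing of the silencer siRNAs: 2 of the 2 7-mers occur in the 3306-base LINC00886 transcript, 24 bases apart in exon 3 (chromosome 3, 156748704 to 156748710 and 156748680 to 156748686). From the share of all scanned 7-mers found in it, 2.94% of pairs would be expected. That share gives rare 7-mers the same weight, so for 7-mers as common as these the expectation may be too low. At least 1 of the 2 7-mers was in 27.9% of the 2-fold lower, 27.6% of the 2-fold higher and 24.1% of all genes scanned. They thus do not set the 2-fold lower genes apart as a whole, without matching on UTR length. Among the 12 lowest mRNA genes, IL11, LRRC15, PI3, PFKFB4, S100A10 and TP53INP2 held at least 1 of them. C12orf57, RND2, CRABP2, TM4SF19 and CKB held neither, and PAPL had no match in the annotation. Among the 12 highest, FBN1, GREM1, ADAM19 and SLIT2 held at least 1. For TCGGAGA the candidate explanation is seed pairing of the control siRNA, in the control library. TCGGAGA is absent from LINC00886 and pairs with bases 2 to 8 of 1 strand, the sense strand (UUCUCCGAACGUGUCACGU), of a scrambled control siRNA in wide use. However, the match of the antisense strand, TGTCACG (297 genes), had a standardized value of only 1.44 and ranked 1805 from the highest. The labels give neither the control nor the silencer sequences. TCGGAGA was in 8.37% of the 2-fold higher genes scanned against 2.20% of all, so most of those genes lack it, and GGAGAAA still stood at 6.90 among the 9307 genes without it, which pairing of those bases leaves open.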
